A study of Homo sapiens with 60 samples.

How the data were processed

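The series measured messenger RNA in HepG2 cells treated for 24 h with herbal extracts at 500, 100 or 20 µg/mL, or with vehicle (dimethyl sulfoxide, 0.1% in the sample labels and 2% in the series design text). Per the labels, libraries were made with a directional RNA kit from RNA with an integrity number above 7 and sequenced as 100 bp paired ends. The deposited table holds expected counts, estimated reads per gene that are not normalised for depth or gene length, for 60675 Ensembl genes in 270 columns. The unit was read from the values, since 8.58% of them are not whole numbers. The submitters' processing notes name FastQC 0.11.9, Trim Galore 0.6.5, STAR 2.7.3a and RSEM 1.3.3 and the build GRCh38, with no annotation release. Only the 60 columns labelled as vehicle or with an extract and dose were used, and the other 210 were not. Symbols and positions came from GENCODE release 29 and a table of gene names, and 57055 of the Ensembl IDs were found in that release.

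Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr with the 19 groups, which left 16167, libraries were scaled by TMM (factors 0.834 to 1.05), and 1 quasi-likelihood model with a mean per group was fitted to 57 libraries (common dispersion 0.00312). Contrasts were each of 6 extracts at each dose against vehicle, the linear dose trend of each extract, and the 3 pairs of extracts that share a set at 500 µg/mL. The quasi-likelihood F test was two-sided, p-values were adjusted by Benjamini-Hochberg within a contrast, and adjusted p under 0.05 was called. Differences between dose trends were tested as contrasts of the same model. Gene lists, 25 in number with 531 genes of which 469 were tested, were tested with camera in limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the 150 pairs of list and extract in each family, and again with a correlation estimated per list. List members were also adjusted over the list alone. The lists, the contrasts, the rule for named genes and all alternatives but 4 were fixed before the data were examined. Named are, per extract at 500 µg/mL, the 8 genes with the largest change in each direction (5 for a pair of extracts) with an adjusted p under 0.05, a mean of at least 2 CPM, a gene symbol and no overlap between the libraries compared, and up to 4 members of each list by adjusted p. Other members of the lists are named where the text groups them. Some genes that meet this rule are not reported here. The coordinates given in the results are those of genes that recur across comparisons.

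Similarity of extracts was Pearson's r across genes between dose trends of log2 CPM (prior count 2), with a two-sided exact permutation p over the 1680 assignments of 9 libraries to 3 doses, adjusted over 15 pairs. Palmul-tang, with 1 library per dose, was described by log2 ratios to the vehicle mean, and its lists beside 10000 random lists matched on expression. Its correlations with fold changes of both formulas stand beside those of simulated unchanged groups with a shared vehicle. Correlations with fold changes that share the vehicle are raised by it, and genes are not independent replicates. The alternatives were size factors by RLE, no filter on low counts, the Wald test of DESeq2 1.42.0, the replicate number as a block, only the compared groups in the fit, and leaving out each library. Alternatives chosen after seeing the data were the mean of the 6 groups at 20 µg/mL as comparator, extracts at 20 µg/mL against each other, the replicate 1 libraries of set 6 left out together, and the genes shared at 20 µg/mL with only the compared groups in each fit. Other groupings of the same libraries were counted with limma-trend.

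The fit was tested on simulated data with the depths and dispersions of these libraries and 200 changed genes. At 500 µg/mL against vehicle it recovered 34%, 86%, 100% and 100% of genes changed 1.2, 1.5, 2 and 3-fold, with 7 false calls among 167. An unchanged contrast gave 0 calls by edgeR. Total counts of 16.5 to 34.4 M per library bound the counting error of each CPM value, which for genes with few reads, such as HAMP in treated groups, can exceed the SD printed.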

Results

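RNA was sequenced from HepG2 cells, a human liver carcinoma line, after 24 h with a water extract of a herbal medicine or with vehicle. There were 4 single herbs (Cnidii Rhizoma, Rehmanniae Radix Preparata, Cinnamomi Cortex and Astragali Radix) and 3 multi-herb formulas (Sagunja-tang, Samul-tang and Palmul-tang). Each extract was given at 500, 100 and 20 µg/mL. The vehicle group and each dose of the 4 herbs, of Sagunja-tang and of Samul-tang had 3 libraries, so that 57 libraries in 19 groups entered the tests. Palmul-tang had 1 library per dose and no replicates. Total counts per library ran from 16.5 M (Astragali Radix at 500 µg/mL, replicate 1) to 34.4 M (Sagunja-tang at 500 µg/mL, replicate 2), with a median of 25.5 M. The first number of the sample codes, called the set here, was 5 for Cnidii Rhizoma and Rehmanniae Radix Preparata. It was 6 for Cinnamomi Cortex and Astragali Radix and 7 for Sagunja-tang and Samul-tang. The labels do not say what it stands for, and all titles, vehicle included, name the same batch, BatchB. The codes of the vehicle libraries hold none of these set numbers, so a difference from vehicle also holds any difference between sets. It may also hold a difference in solvent. The dose trend of an extract, in contrast, compares libraries of 1 set. Nothing in the labels says whether the 3 replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

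Of 16167 genes tested, Cinnamomi Cortex at 500 µg/mL changed 10141 against vehicle, the highest count of the 6 extracts, and a principal component that carried 24.3% of the variance set its libraries apart from all others. At that dose the counts were 2212 for Samul-tang, 1985 for Sagunja-tang, 1904 for Cnidii Rhizoma, 1204 for Rehmanniae Radix Preparata and 492 for Astragali Radix. A dose trend, the log2 change per 5-fold dose step over the 3 doses, was called for 10010 genes with Cinnamomi Cortex, 1597 with Samul-tang, 807 with Sagunja-tang, 520 with Cnidii Rhizoma, 187 with Astragali Radix and 109 with Rehmanniae Radix Preparata. Fold changes below are log2 values ± SE from the edgeR fit, with n = 3 libraries per group and 9 per dose trend. Expression levels are read counts scaled to library size (CPM) ± SD, n = 3. Every gene named for its size of change had all 3 treated libraries on 1 side of all 3 libraries it was compared with, which 10% of unchanged genes would show by chance. Positions are on GRCh38: HAMP (ENSG00000105697, chromosome 19, 35280716 to 35285143), MT1G (ENSG00000125144, chromosome 16, 56666731 to 56668065), CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408), IGFBP1 (ENSG00000146678, chromosome 7, 45888357 to 45893668), PFKFB3 (ENSG00000170525, chromosome 10, 6144934 to 6254644) and ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794). All of these are annotated as protein-coding genes.

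**Figure D1:**
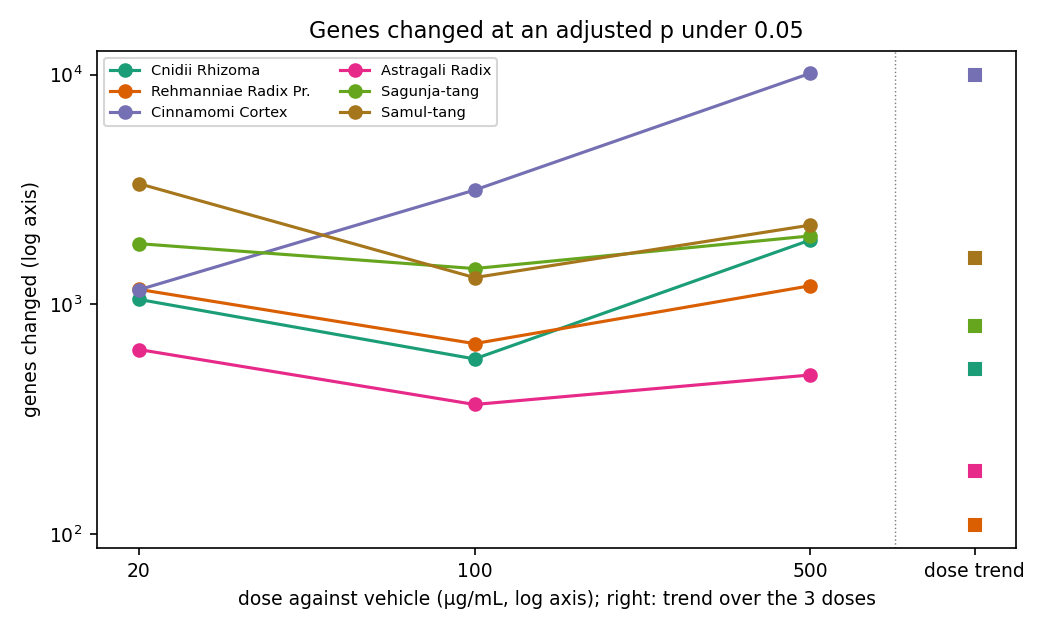
Number of genes changed at an adjusted p under 0.05 (log axis) against vehicle at 20, 100 and 500 µg/mL (log axis), 1 line per extract, and on the right the number with a dose trend. Cinnamomi Cortex climbs from 1157 to 10141 genes, and in this fit of all groups Samul-tang has 3353 at 20 and 2212 at 500 µg/mL, an order that turned round with only the compared groups in the fit (142 and 1479).

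Cinnamomi Cortex at 500 µg/mL raised genes of low oxygen, glycolysis, amino acid stress and oxidant defence and lowered genes of DNA replication and cell division. IGFBP1, a secreted insulin-like growth factor binding protein, went from 121 ± 14 to 3590 ± 305 CPM, a log2 fold change of 4.89 ± 0.2 (adjusted p = 3.55e-26). IGFBP3 rose by 5.26 ± 0.2. HAMP, which encodes the iron hormone hepcidin, fell by 4.80 on the log2 scale, from 6.48 ± 1.04 to 0.227 ± 0.0695 CPM. Of the 10141 genes changed, 5027 were higher and 5114 lower, and 2513 of them changed at least 2-fold.

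Other genes with large rises were TNS1 (4.13 ± 0.19), a focal adhesion protein, the AP-1 transcription factors FOS (3.89 ± 0.18) and FOSB (3.83 ± 0.27), the carbonic anhydrase CA9 (3.55 ± 0.17) and the pseudogene RASA4CP (3.87 ± 0.29). The largest falls beside HAMP were in MT1G (-4.90 ± 0.17), MT1F (-4.48 ± 0.16), CENPE (-3.43 ± 0.16), a kinetochore motor, MT1E (-3.09 ± 0.11), SEC31B (-3.06 ± 0.23), CCDC144NL (-3.02 ± 0.16) and LRRCC1 (-2.98 ± 0.21). All of these genes had a dose trend in the same direction, such as 1.88 ± 0.095 per step for IGFBP1 and -2.25 ± 0.084 for MT1G.

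On the hypoxia and glycolysis list, 29 of 29 measured members rose (29 adjusted over the list alone), with a median of 1.49 (adjusted p = 4.02e-32). Examples were ADM (3.06 ± 0.12) and the aldolases ALDOA (1.46 ± 0.052) and ALDOC (1.80 ± 0.067). Among genes of the ATF4 integrated stress response, 22 of 23 measured members rose (23 adjusted over the list alone, adjusted p = 1.13e-18), including asparagine synthetase ASNS (1.61 ± 0.05), DDIT4 (2.22 ± 0.11), PPP1R15A (1.85 ± 0.079) and TRIB3 (1.56 ± 0.068). For NRF2 antioxidant genes, 19 of 21 measured members rose (19 adjusted over the list alone) and 2 fell (adjusted p = 1.14e-15). The cystine transporter SLC7A11 rose by 2.32 ± 0.07, the aldo-keto reductase AKR1B10 by 2.29 ± 0.067 and GCLC, an enzyme of glutathione synthesis, by 1.47 ± 0.043. In the NF-kB and chemokine list 10 of 15 measured members rose (10 adjusted over the list alone) and 1 fell (adjusted p = 9.88e-06), with IER3 at 1.83 ± 0.073, CCL20 at 1.99 ± 0.1 and ICAM1 at 1.02 ± 0.047. In the gluconeogenesis and FOXO list 10 of 13 measured members rose (10 adjusted over the list alone, adjusted p = 0.000671), among them PCK1 (1.84 ± 0.1) and G6PC1 (1.42 ± 0.1). Cholesterol synthesis genes rose in 17 of 22 cases (18 adjusted over the list alone, adjusted p = 1.08e-05), DHCR7 (1.06 ± 0.072) among them. The PPARA list was higher (10 of 18 rose, 10 adjusted over the list alone, 5 fell, adjusted p = 0.0191), with the lipid droplet protein PLIN2 at 2.65 ± 0.1, ANGPTL4 at 1.96 ± 0.13 and CPT1A at 1.48 ± 0.067.

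All 26 measured DNA replication genes fell (26 adjusted over the list alone), with a median of -1.23 (adjusted p = 7.29e-30). MCM3 changed by -1.37 ± 0.046, MCM4 by -1.33 ± 0.051 and UHRF1 by -1.52 ± 0.055. On the mitosis list 26 of 26 measured members fell (26 adjusted over the list alone), with a median of -1.31 (adjusted p = 3.51e-39), including TOP2A (-2.09 ± 0.06), KIF20A (-1.66 ± 0.059) and BUB1B (-1.56 ± 0.056). Metallothioneins and zinc export genes, which bind or remove metal ions, fell in 7 of 8 cases (7 adjusted over the list alone, median -2.79, adjusted p = 2.68e-09). Genes of secreted liver proteins rose in 17 of 26 cases (17 adjusted over the list alone) and fell in 6 (adjusted p = 0.0125, but adjusted p = 0.21 with an estimated correlation). Ribosomal protein genes rose in 41 of 54 (41 adjusted over the list alone, adjusted p = 0.0146, but 0.54 with an estimated correlation). Of 10 measured markers of other cell types, 5 rose and 3 fell, with a median of 0.67 and no call for the list (adjusted p = 0.0927). Mitochondrial transcripts took 21.9%, 22.3% and 19.4% of the counts in replicates 1, 2 and 3 at 500 µg/mL, beside 14.6%, 14.4% and 16.7% in vehicle, and the TMM factors were 0.839, 0.834 and 0.863. The count at 100 µg/mL was 3144 and no single library moved the counts at 500 or 100 µg/mL or the trend by more than 1.5 times.

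The herbs of set 6 were compared at the same dose within 1 set. At 500 µg/mL, 10131 genes differed between Cinnamomi Cortex and Astragali Radix, 4990 higher and 5141 lower with Cinnamomi Cortex. IGFBP3 (5.11 ± 0.2), IGFBP1 (4.86 ± 0.2), RASA4CP (4.79 ± 0.34) and FOS (4.12 ± 0.19) were among the most raised. HAMP (-4.60 ± 0.28), MT1G (-4.16 ± 0.17), CENPE (-3.59 ± 0.16), MT1F (-3.47 ± 0.18) and SEC31B (-3.18 ± 0.23) were the most lowered. All of these calls held without each single library. The dose trends themselves differed for 8230 genes.

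Astragali Radix at 500 µg/mL lowered metallothioneins and genes of lipid synthesis and raised NRF2, heat shock and unfolded protein response genes. MT1F fell by 1.02 on the log2 scale (SE 0.11, adjusted p = 5.77e-08), MT2A changed by -0.75 ± 0.12, MT1G by -0.74 ± 0.11 and MT1E by -0.67 ± 0.099. G6PC1, the last enzyme of glucose release, changed by -0.62 ± 0.11 and had a dose trend of -0.44 ± 0.056 per step. The heat shock genes HSPA1A (0.76 ± 0.11) and HSPA1B (0.69 ± 0.099), near-identical copies whose reads can be shared, were higher. In all, 492 genes changed, 253 higher and 239 lower, 27 of them at least 2-fold.

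On the metallothionein list 6 of 8 measured members fell (8 adjusted over the list alone), with a median of -0.70 (adjusted p = 2.47e-21). For cholesterol synthesis 7 of 22 measured members fell (12 adjusted over the list alone, adjusted p = 1.03e-14), with FDFT1 at -0.31 ± 0.038 and HMGCS1 at -0.29 ± 0.057. For fatty acid synthesis 4 of 18 measured members fell (4 adjusted over the list alone, adjusted p = 1.11e-09), with ACSS2 at -0.38 ± 0.039 and LPIN1 at -0.29 ± 0.053. NRF2 genes rose in 4 of 21 cases (6 adjusted over the list alone, adjusted p = 3.88e-07), such as AKR1B10 (0.39 ± 0.069) and AKR1C2 (0.38 ± 0.058). Heat shock genes rose in 5 of 16 (11 adjusted over the list alone, adjusted p = 3.78e-13) and genes of the unfolded protein response in 4 of 18 (10 adjusted over the list alone, adjusted p = 4.6e-09). In the ATF4 list 2 fell, among them ASNS (-0.44 ± 0.053), and 1 rose (4 and 2 adjusted over the list alone, adjusted p = 0.0151, but adjusted p = 0.128 with an estimated correlation). The mitosis list was called higher with no member called over all genes or over the list alone (adjusted p = 0.00763, but 0.214 with an estimated correlation). The acute phase list was lower with 1 member called (2 lower and 1 higher adjusted over the list alone, adjusted p = 0.0472, but adjusted p = 0.21 with an estimated correlation). The calls of the ATF4 and acute phase lists ended without 1 vehicle library: ATF4 without replicate 2 (adjusted p = 0.0808), and acute phase without replicate 1 (0.0696) or 2 (0.0797). The ATF4 call also ended without the replicate 1 libraries of set 6, left out after seeing the data (adjusted p = 0.0754). The acute phase call also ended under RLE size factors (adjusted p = 0.053) and with the replicate number as a block (0.0523). The unfolded protein response list had no dose trend (adjusted p = 0.235), and the trend of the heat shock list, with 0 members called (0 adjusted over the list alone, adjusted p = 0.033), was lost at adjusted p = 0.206 with an estimated correlation.

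The replicate 1 libraries of set 6 stood apart from replicates 2 and 3 in hypoxia genes. With Astragali Radix, PFKFB3, a regulator of glycolysis, was at 2.47, 2.14 and 2.29 CPM in replicate 1 at 500, 100 and 20 µg/mL, beside 5.15 and 5.52, 7.12 and 7.46, and 5.95 and 6.07 CPM in replicates 2 and 3. Vehicle was at 2.54 ± 0.3 CPM. The median of the hypoxia list over the vehicle mean was -0.10, 0.00 and 0.05 in replicate 1 and between 0.10 and 0.28 in the other 6 libraries of this herb. Replicate 1 was the lowest of 3 in all 6 groups of set 6, which 3 of 729 equally likely assignments would show for any 1 number (exact p = 0.00412). The test was chosen after this had been seen. For the same measure replicate 3 was lowest in 5 of 6 groups of set 7 (exact p = 0.0535) and in 4 of 6 of set 5 (exact p = 0.3). Without the 6 replicate 1 libraries of set 6, a choice made after seeing the data, 461 genes changed with Astragali Radix at 500 µg/mL, and the count with a dose trend went from 187 to 110. The hypoxia list, not called for Astragali Radix with all libraries (adjusted p = 0.3), was then higher, with 6 of 29 genes up and a median of 0.10 (adjusted p = 2.77e-07). Its dose trend was lower, by a median of -0.04 per step with 0 genes rising and 2 falling (adjusted p = 3.85e-07).

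Of the other genes with the largest change, HES4 (0.90 ± 0.22), TRIM8-DT (0.78 ± 0.22), SYCP3 (0.78 ± 0.18), FAM13A (0.73 ± 0.19), HELB (0.67 ± 0.14) and CHROMR (0.64 ± 0.15) were higher. CCDC144NL (-0.63 ± 0.12), PBLD (-0.60 ± 0.14) and TRIM36 (-0.60 ± 0.16) were lower. None of these 9 had a dose trend. The calls of HES4 (0.85 without vehicle replicate 3, 0.75 without treated replicate 2), TRIM8-DT (0.74 and 0.71 without vehicle replicates 1 and 2, 0.63 and 0.83 without treated replicates 2 and 3) and SYCP3 (0.70 without vehicle replicate 2, 0.70 without treated replicate 2) ended without 1 library. The same held for FAM13A (0.64 without vehicle replicate 1, 0.73 and 0.50 without treated replicates 2 and 3), HELB (0.51 without treated replicate 2) and CHROMR (0.55 without vehicle replicate 1, 0.55 without treated replicate 3). This was also so for PBLD (-0.54 without vehicle replicate 2, -0.57 and -0.60 without treated replicates 2 and 3) and TRIM36 (-0.57, -0.62 and -0.61 without vehicle replicates 1, 2 and 3, -0.47 and -0.53 without treated replicates 2 and 3). With the mean of the groups at 20 µg/mL as comparator, in place of vehicle, a comparator chosen after seeing the data, the calls of HES4 (0.01), TRIM8-DT (-0.11), SYCP3 (0.09), HSPA1A (-0.16), FAM13A (-0.16), HSPA1B (-0.07), HELB (0.17), CHROMR (0.14), CCDC144NL (0.13), PBLD (-0.28), TRIM36 (0.14) and HMGCS1 (-0.10) ended, with only the 2 groups compared in the fit those of FAM13A (0.73), PBLD (-0.60) and TRIM36 (-0.60), and without a filter on low counts that of TRIM36 (-0.61). The count of 492 went to 223, 298 and 314 without vehicle replicates 1, 2 and 3 and 208 and 252 without treated replicates 2 and 3. The count of 187 trends went to 106 and 121 without replicates 1 and 2 at 500 and 110 and 101 without replicates 2 and 3 at 20. Other choices gave 278 with only the compared groups in the fit, 1290 against the mean of the groups at 20 µg/mL, 97 for the trend with only the compared groups in the fit and 292 for the trend with no filter on low counts.

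Cnidii Rhizoma at 500 µg/mL lowered HAMP, the metallothioneins and lipid synthesis genes with dose, and raised hypoxia genes without a dose trend. HAMP went from 6.48 ± 1.04 to 1.5 ± 0.447 CPM, a log2 fold change of -2.10 ± 0.18 (adjusted p = 7.01e-12), with a dose trend of -0.93 ± 0.092 per step. MT1G changed by -1.51 ± 0.12, MT1F by -1.42 ± 0.11, MT1E by -1.22 ± 0.1, MT2A by -1.17 ± 0.12 and MT1X by -0.88 ± 0.11. PFKFB3 rose by 2.11 ± 0.29, from 2.54 ± 0.3 to 10.9 ± 0.948 CPM, and was at 10.3 ± 1.78 CPM at 20 µg/mL. In all, 1904 genes changed, 987 higher and 917 lower, 130 of them at least 2-fold.

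For cholesterol synthesis 17 of 22 measured members fell (18 adjusted over the list alone, adjusted p = 2.44e-21), with HMGCS1 at -0.51 ± 0.058 and IDI1 at -0.44 ± 0.056. For fatty acid synthesis 12 of 18 measured members fell (15 adjusted over the list alone, adjusted p = 3.92e-22), with ACSS2 at -0.59 ± 0.039 and the desaturase SCD at -0.40 ± 0.043. On the metallothionein list 7 of 8 measured members fell (7 adjusted over the list alone), with a median of -1.2 (adjusted p = 9.75e-34). NRF2 genes rose in 14 of 21 cases (15 adjusted over the list alone, adjusted p = 1.16e-18), with AKR1B10 at 1.04 ± 0.067 and AKR1C2 at 0.50 ± 0.058. Hypoxia genes rose in 19 of 29 (20 adjusted over the list alone, adjusted p = 1.11e-18), but the list had no dose trend (adjusted p = 0.818). Examples were the hexokinase HK2 (0.72 ± 0.082), PDK1 (0.72 ± 0.11) and VEGFA (0.40 ± 0.062). Heat shock (7 of 16, 8 adjusted over the list alone, adjusted p = 8.29e-07) and unfolded protein response genes (7 of 18, 8 adjusted over the list alone, adjusted p = 4.26e-05) also rose without a trend for the list. In the bile acid list 3 of 11 rose (3 adjusted over the list alone, adjusted p = 0.0227): the transporter subunit SLC51A (0.62 ± 0.075), NR0B2 (0.55 ± 0.11) and BAAT (0.31 ± 0.1). Acute phase genes fell in 4 of 17 (5 adjusted over the list alone, adjusted p = 0.00019), HAMP and CFB (-0.26 ± 0.037) among them. Mitochondrially encoded mRNAs were higher in 3 of 13 (10 adjusted over the list alone, adjusted p = 2.52e-05, but 0.298 with an estimated correlation). All mitochondrial transcripts took 22.6% of the counts in replicate 1, the highest of all libraries. Ribosomal protein genes rose in 7 of 54 (12 adjusted over the list alone, adjusted p = 0.00123, but 0.407 with an estimated correlation, and 0.159 without vehicle replicate 3).

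The other genes with the largest rises were the small nuclear RNA 7SK (1.83 ± 0.42), CALCRL-AS1 (1.70 ± 0.26), the pseudogene HMGN2P5 (1.41 ± 0.25), TMCC1 (1.39 ± 0.17), ANKRD37 (1.38 ± 0.26), FAM13A (1.29 ± 0.18) and MIR210HG (1.29 ± 0.25), the host gene of a hypoxia-induced microRNA. None of these, nor PFKFB3, had a dose trend. The kinase gene SGK1 (-0.82 ± 0.083) and the pro-apoptotic gene BMF (-0.80 ± 0.078) fell, both with a trend. The call of BAAT (0.28 and 0.28 without vehicle replicates 2 and 3, 0.21 and 0.34 without treated replicates 1 and 3) ended without 1 library. BAAT also lost its call in a fit with only the 2 groups compared (0.31). Measured from the mean of the groups at 20 µg/mL, the calls of 7SK (0.52), NR0B2 (-0.13) and BAAT (0.02) ended. The count of 1904 went to 937 without vehicle replicate 1 and 1093 and 1130 without treated replicates 1 and 3. The count of 520 trends went to 304 and 226 without replicates 1 and 3 at 500 and 286, 282 and 256 without replicates 1, 2 and 3 at 20. Other choices gave 752 with only the compared groups in the fit and 320 for the trend with only the compared groups in the fit.

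Rehmanniae Radix Preparata at 500 µg/mL raised NRF2 genes with dose and lowered HAMP, with no call for the metallothioneins. HAMP went to 1.28 ± 0.2 CPM, a log2 fold change of -2.34 ± 0.18 (adjusted p = 1.1e-12), with a dose trend of -0.82 ± 0.1 per step. ID3, a target of BMP signalling, changed by -0.84 ± 0.12 (trend -0.40 ± 0.06), and the aldehyde dehydrogenase ALDH3A1 rose by 0.94 ± 0.19 (trend 0.62 ± 0.1). PFKFB3 (1.96 ± 0.29) and ANKRD37 (1.3 ± 0.26) rose without a trend. In all, 1204 genes changed, 625 higher and 579 lower, 53 of them at least 2-fold.

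NRF2 genes rose in 15 of 21 cases (17 adjusted over the list alone, adjusted p = 6.75e-30), with AKR1B10 at 0.68 ± 0.068, GCLM at 0.64 ± 0.077, SLC7A11 at 0.62 ± 0.072 and PIR at 0.60 ± 0.067. Hypoxia genes rose in 15 of 29 (19 adjusted over the list alone, adjusted p = 1.37e-17), with no trend for the list (adjusted p = 0.763). Heat shock genes rose in 5 of 16 (6 adjusted over the list alone, adjusted p = 4.15e-07) and unfolded protein response genes in 4 of 18 (13 adjusted over the list alone, adjusted p = 1.49e-05). Neither list had a dose trend (adjusted p = 0.289 and 0.54). DNA replication genes fell in 9 of 26 (14 adjusted over the list alone, adjusted p = 2.68e-09), with PCNA at -0.37 ± 0.058 and MCM3 at -0.22 ± 0.044, and no trend for the list (adjusted p = 0.884). Cholesterol synthesis genes fell in 4 of 22 (4 adjusted over the list alone, adjusted p = 0.000223). The fatty acid synthesis list fell too (4 of 18, 6 adjusted over the list alone, adjusted p = 9.23e-05). Its called members ARRDC4 and TXNIP (-0.36 ± 0.043) are not synthesis enzymes. Acute phase genes fell in 6 of 17 and rose in 1 (7 and 2 adjusted over the list alone, adjusted p = 0.000149). YAP and TGF-beta targets fell in 6 of 16 and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00616), with ANKRD1 at -0.64 ± 0.1 and CCN1 at -0.55 ± 0.1. Mitochondrially encoded mRNAs were called higher (adjusted p = 0.000534, but 0.406 with an estimated correlation). No single member was called over all genes and 3 over the list alone. On the metallothionein list 0 of 8 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of 0.02 (adjusted p = 0.965).

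The remaining genes with the largest rises were TMCC1 (1.14 ± 0.17), FAM13A (1.11 ± 0.18), the pseudogene ANAPC1P4 (1.09 ± 0.25) and PPP2R2C (1.05 ± 0.16). Those with the largest falls were the pseudogenes RPS3AP26 (-1.02 ± 0.23) and SMG1P2 (-0.78 ± 0.19), HTD2 (-0.89 ± 0.22), SGMS1-AS1 (-0.75 ± 0.18), the small nucleolar RNA SNORD3B-1 (-0.74 ± 0.2) and CCDC144NL (-0.71 ± 0.11). Without 1 library the calls of ANAPC1P4 (0.85 without vehicle replicate 1), RPS3AP26 (-0.67 without vehicle replicate 1) and HTD2 (-0.77 without vehicle replicate 1, -0.70 without treated replicate 2) ended. Equally affected were SNORD3B-1 (-0.66 without vehicle replicate 2, -0.66 and -0.70 without treated replicates 1 and 2). Beside the mean of the groups at 20 µg/mL the calls of ANKRD37 (0.57), TMCC1 (0.34), FAM13A (0.22), PPP2R2C (0.21), RPS3AP26 (-0.39), HTD2 (-0.22), SMG1P2 (-0.46), SGMS1-AS1 (-0.36), SNORD3B-1 (-0.28), CCDC144NL (0.05), PCNA (-0.06), MCM3 (-0.10), ANKRD1 (-0.23) and CCN1 (-0.18) ended. The count of 1204 went to 536 without vehicle replicate 1 and 631 and 768 without treated replicates 1 and 2. The count of 109 trends went to 69 without replicate 3 at 500. Other choices gave 537 against the mean of the groups at 20 µg/mL and 281 for the trend with no filter on low counts.

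Both herbs of set 5 are traditional parts of Samul-tang. At 500 µg/mL they differed in 114 genes, 57 higher and 57 lower with Cnidii Rhizoma. Metallothioneins were lower with Cnidii Rhizoma: MT1G by -1.58 ± 0.12, MT1F by -1.19 ± 0.12, MT2A by -1.19 ± 0.12 and MT1E by -1.17 ± 0.1. ALDH3A1 was lower too (-1 ± 0.19). WDR5B-DT (0.72 ± 0.17), the respiratory chain gene NDUFA1 (0.62 ± 0.15), LEAP2 (0.60 ± 0.11), the arginase ARG1 (0.57 ± 0.15) and the apolipoprotein APOC3 (0.52 ± 0.1) were higher. The dose trends differed for 11 genes, 10 with the lower trend for Cnidii Rhizoma, among them MT1G (-0.85 ± 0.08 per step) and ACSS2 (-0.20 ± 0.028). Calls lost with 1 library left out were those of WDR5B-DT (0.74 and 0.62 without Rehmanniae Radix Preparata replicates 1 and 3, 0.64 and 0.68 without Cnidii Rhizoma replicates 2 and 3), NDUFA1 (0.47 and 0.60 without Rehmanniae Radix Preparata replicates 1 and 2, 0.45 without Cnidii Rhizoma replicate 3) and ARG1 (0.60, 0.59 and 0.51 without Cnidii Rhizoma replicates 1, 2 and 3, 0.51, 0.63 and 0.56 without Rehmanniae Radix Preparata replicates 1, 2 and 3). The same held for APOC3 (0.37 without Cnidii Rhizoma replicate 1) and ALDH3A1 (-0.88 without Cnidii Rhizoma replicate 3). With only these 2 groups in the fit, 19 genes passed and the calls of WDR5B-DT (0.72), NDUFA1 (0.62), ARG1 (0.57), APOC3 (0.53) and ALDH3A1 (-1) ended. The count of 114 went to 45 and 52 without Rehmanniae Radix Preparata replicates 1 and 2 and 246 and 42 without Cnidii Rhizoma replicates 2 and 3.

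Sagunja-tang at 500 µg/mL raised the aryl hydrocarbon receptor (AHR) target CYP1A1 and NRF2 genes with dose and lowered metallothioneins and lipid synthesis genes. CYP1A1, an enzyme of xenobiotic metabolism, went from 11.8 ± 1.03 to 56 ± 3.38 CPM, a log2 fold change of 2.25 ± 0.094 (adjusted p = 1.3e-23), with a dose trend of 1.15 ± 0.047 per step. ALDH3A1 rose by 1.2 ± 0.18 (trend 0.84 ± 0.096) and AKR1B10 by 0.96 ± 0.067 (trend 0.54 ± 0.034). HAMP changed by -1 ± 0.16 (trend -0.36 ± 0.079) and GNMT, a glycine methyltransferase, by -0.91 ± 0.13. In all, 1985 genes changed, 1093 higher and 892 lower, 63 of them at least 2-fold.

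In the AHR list 2 of 7 rose, CYP1A1 and ALDH3A1 (2 adjusted over the list alone, adjusted p = 5.67e-07). NRF2 genes rose in 11 of 21 cases (14 adjusted over the list alone, adjusted p = 9.13e-22), with GCLM at 0.68 ± 0.077 and NQO1 at 0.50 ± 0.05. On the metallothionein list 6 of 8 measured members fell (7 adjusted over the list alone), with a median of -0.77 (adjusted p = 1.28e-15). MT1F changed by -1.16 ± 0.11, MT1G by -0.83 ± 0.11 and MT1E by -0.78 ± 0.098. Cholesterol (11 of 22, 13 adjusted over the list alone, adjusted p = 5.68e-07) and fatty acid synthesis genes (8 of 18, 8 adjusted over the list alone, adjusted p = 1.57e-06) fell, with ACSS2 at -0.48 ± 0.039 and FDFT1 at -0.27 ± 0.038. Mitosis genes rose in 10 of 26 (12 adjusted over the list alone, adjusted p = 2.34e-05), with MKI67 at 0.31 ± 0.085 and KIF20A at 0.26 ± 0.053. NF-kB targets rose in 4 of 15 and fell in 1 (4 and 1 adjusted over the list alone, adjusted p = 0.0182), with BIRC3 at 0.74 ± 0.12 and CCL20 at 0.63 ± 0.1. Heat shock genes (9 of 16, 11 adjusted over the list alone, adjusted p = 1.9e-10) and unfolded protein response genes (12 of 18, 13 adjusted over the list alone, adjusted p = 1.62e-09) rose without a trend for either list. Acute phase genes fell in 8 of 17 (10 adjusted over the list alone, adjusted p = 7.5e-07). Secreted liver proteins fell in 6 of 26 and rose in 1 (9 and 1 adjusted over the list alone, adjusted p = 0.00126, but 0.0967 with an estimated correlation). Albumin, ALB, was at -0.26 ± 0.066. Hypoxia genes rose in 6 of 29 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00476, but 0.47 with an estimated correlation).

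Further genes with large changes were 7SK (1.46 ± 0.42), TMCC1 (1.05 ± 0.17), PPP2R2C (0.96 ± 0.16), HES4 (0.94 ± 0.21) and ANAPC1P4 (0.93 ± 0.25) upward. Large falls were seen for SNORD3B-1 (-1.02 ± 0.2) and PTP4A3 (-0.85 ± 0.14). The calls of 7SK (1.31 without vehicle replicate 3, 0.75 without treated replicate 2), HES4 (0.64 without treated replicate 2) and ANAPC1P4 (0.69 without vehicle replicate 1, 0.72 without treated replicate 2) ended without 1 library. This was also so for MKI67 (0.28 without vehicle replicate 1, 0.21 and 0.28 without treated replicates 1 and 3). Relative to the mean at 20 µg/mL over 6 extracts the calls of 7SK (0.15), TMCC1 (0.25), PPP2R2C (0.12) and HES4 (0.05) ended, and with only the 2 groups compared in the fit those of ANAPC1P4 (0.93), ALB (-0.26) and MKI67 (0.30). The count of 1985 went to 1252 without vehicle replicate 2 and 1225 without treated replicate 1. The count of 807 trends went to 473 without replicate 1 at 500 and 432 and 425 without replicates 2 and 3 at 20. Other choices gave 1014 with only the compared groups in the fit.

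Samul-tang at 500 µg/mL lowered HAMP together with the BMP signalling targets ID1 and ID3, and raised CYP1A1. HAMP, itself driven by BMP signalling, went from 6.48 ± 1.04 to 0.413 ± 0.0476 CPM, a log2 fold change of -3.95 ± 0.23 (adjusted p = 7.81e-18). ID3 changed by -1.67 ± 0.13 and ID1 by -0.98 ± 0.094. CYP1A1 rose by 2.73 ± 0.094 to 78.6 ± 1.64 CPM, ALDH3A1 by 1.25 ± 0.19 and SLC7A11 by 0.97 ± 0.071. In all, 2212 genes changed, 1203 higher and 1009 lower, 73 of them at least 2-fold.

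One library, Samul-tang at 20 µg/mL replicate 2, decided the number of dose trends: 1597 genes passed with it and 153 without it, beside 2904 and 2812 without replicate 1 or 3 of the same group. The trends of the genes above were similar either way. With and without that library they were, per step, -1.80 and -1.68 for HAMP, -0.97 and -0.88 for ID3, -0.65 and -0.56 for ID1 and 1.18 and 1.24 for CYP1A1. Without replicate 1 or 3 at 500 µg/mL the count was 633 or 575. The median trend of the metallothionein list was -0.37 with the library and -0.33 without it, and that of the NRF2 list 0.10 and 0.12.

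In the AHR list 2 of 7 rose, CYP1A1 and ALDH3A1, and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 1.15e-07). NRF2 genes rose in 9 of 21 cases and fell in 1 (11 and 1 adjusted over the list alone, adjusted p = 4.03e-11), with GCLM at 0.69 ± 0.078, AKR1B10 at 0.55 ± 0.068 and NQO1 at 0.35 ± 0.05. On the metallothionein list 6 of 8 measured members fell (6 adjusted over the list alone), with a median of -0.64 (adjusted p = 1.34e-09), MT1F at -0.92 ± 0.11 among them. Cholesterol (13 of 22, 14 adjusted over the list alone, adjusted p = 4.48e-13) and fatty acid synthesis genes (7 of 18, 9 adjusted over the list alone, adjusted p = 6.35e-07) fell, with FDFT1 at -0.42 ± 0.038, HMGCS1 at -0.38 ± 0.057 and ACSS2 at -0.47 ± 0.039. DNA replication genes fell in 10 of 26 and rose in 1 (17 and 1 adjusted over the list alone, adjusted p = 3.72e-07), PCNA at -0.38 ± 0.058 among them. Secreted liver proteins fell in 11 of 26 and rose in 1 (11 and 1 adjusted over the list alone, adjusted p = 8.64e-06), with transthyretin TTR at -0.38 ± 0.061 and ALB at -0.34 ± 0.066. YAP and TGF-beta targets fell in 7 of 16 and rose in 3 (7 and 5 adjusted over the list alone, adjusted p = 0.0138), with ANKRD1 at -0.84 ± 0.11 and CCN1 at -0.71 ± 0.1. Acute phase genes fell in 3 of 17 and rose in 2 (5 and 2 adjusted over the list alone, adjusted p = 0.00154). Heat shock genes rose in 6 of 16 (7 adjusted over the list alone, adjusted p = 0.000341). The list had no dose trend (adjusted p = 0.818). Unfolded protein response genes rose in 6 of 18 and fell in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.000174, but 0.06 with an estimated correlation). Hypoxia genes rose in 8 of 29 (9 adjusted over the list alone, adjusted p = 4.6e-05, but 0.279 with an estimated correlation). Ribosomal protein genes fell in 14 of 54 (16 adjusted over the list alone, adjusted p = 4.16e-08, but 0.126 with an estimated correlation).

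Other genes with large changes were 7SK (1.49 ± 0.43), PFKFB3 (1.12 ± 0.32), PPP2R2C (1.01 ± 0.17), FAM13A (0.94 ± 0.18) and TMCC1 (0.94 ± 0.17) upward. Large falls were also seen for ZNF821 (-0.84 ± 0.2), RPS3AP26 (-0.83 ± 0.23) and the sodium channel subunit SCNN1A (-0.79 ± 0.086). Without 1 library the calls of 7SK (1.34 without vehicle replicate 3, 0.95 without treated replicate 3), PFKFB3 (1.08 without vehicle replicate 1, 1.03 without treated replicate 1) and RPS3AP26 (-0.48 without vehicle replicate 1) ended. Against the mean of the 6 groups at 20 µg/mL the calls of 7SK (0.18), PFKFB3 (-0.10), PPP2R2C (0.16), FAM13A (0.05), TMCC1 (0.14), RPS3AP26 (-0.19) and PCNA (-0.07) ended, and with only the 2 groups compared in the fit so did that of RPS3AP26 (-0.82). The count of 2212 went to 1436 and 1384 without vehicle replicates 1 and 2 and 1151 without treated replicate 3. Other choices gave 1105 against the mean of the groups at 20 µg/mL and 72 for the trend with only the compared groups in the fit.

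The formulas of set 7 differed from each other at 500 µg/mL in 143 genes, 61 higher and 82 lower with Sagunja-tang. The BMP targets ID3 (1.99 ± 0.13), ID1 (1.29 ± 0.094), ID2 (0.76 ± 0.08) and SMAD7 (0.69 ± 0.089) and GP2 (0.66 ± 0.14) were higher with Sagunja-tang. CA9 (-1.05 ± 0.22), ACKR2 (-0.71 ± 0.16), UNC5CL (-0.66 ± 0.17), KLHL24 (-0.59 ± 0.12) and VLDLR (-0.56 ± 0.13) were lower. The dose trends differed for 23 genes, 18 of them higher with Sagunja-tang, including HAMP (1.43 ± 0.15 per step), ID3 (1.04 ± 0.083), ID1 (0.66 ± 0.064), ID2 (0.39 ± 0.055) and SMAD7 (0.37 ± 0.06). Calls lost with 1 library left out were those of GP2 (0.63 and 0.64 without Samul-tang replicates 1 and 3, 0.60 without Sagunja-tang replicate 2), CA9 (-0.87 without Samul-tang replicate 1) and ACKR2 (-0.56 without Sagunja-tang replicate 2, -0.67 without Samul-tang replicate 3). Equally affected were UNC5CL (-0.48 and -0.74 without Sagunja-tang replicates 1 and 3, -0.69, -0.68 and -0.61 without Samul-tang replicates 1, 2 and 3), KLHL24 (-0.51 without Samul-tang replicate 1) and VLDLR (-0.53 and -0.50 without Sagunja-tang replicates 1 and 3, -0.48 without Samul-tang replicate 1). With only these 2 groups in the fit, 11 genes passed and the calls of GP2 (0.65), CA9 (-1.05), ACKR2 (-0.72), UNC5CL (-0.66), KLHL24 (-0.59) and VLDLR (-0.56) ended. DESeq2 called 217, and without a filter on low counts 233 passed and the call of VLDLR (-0.55) ended. The count of 143 went to 93 and 94 without Sagunja-tang replicates 1 and 2 and 95 and 69 without Samul-tang replicates 1 and 3.

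**Figure D2:**
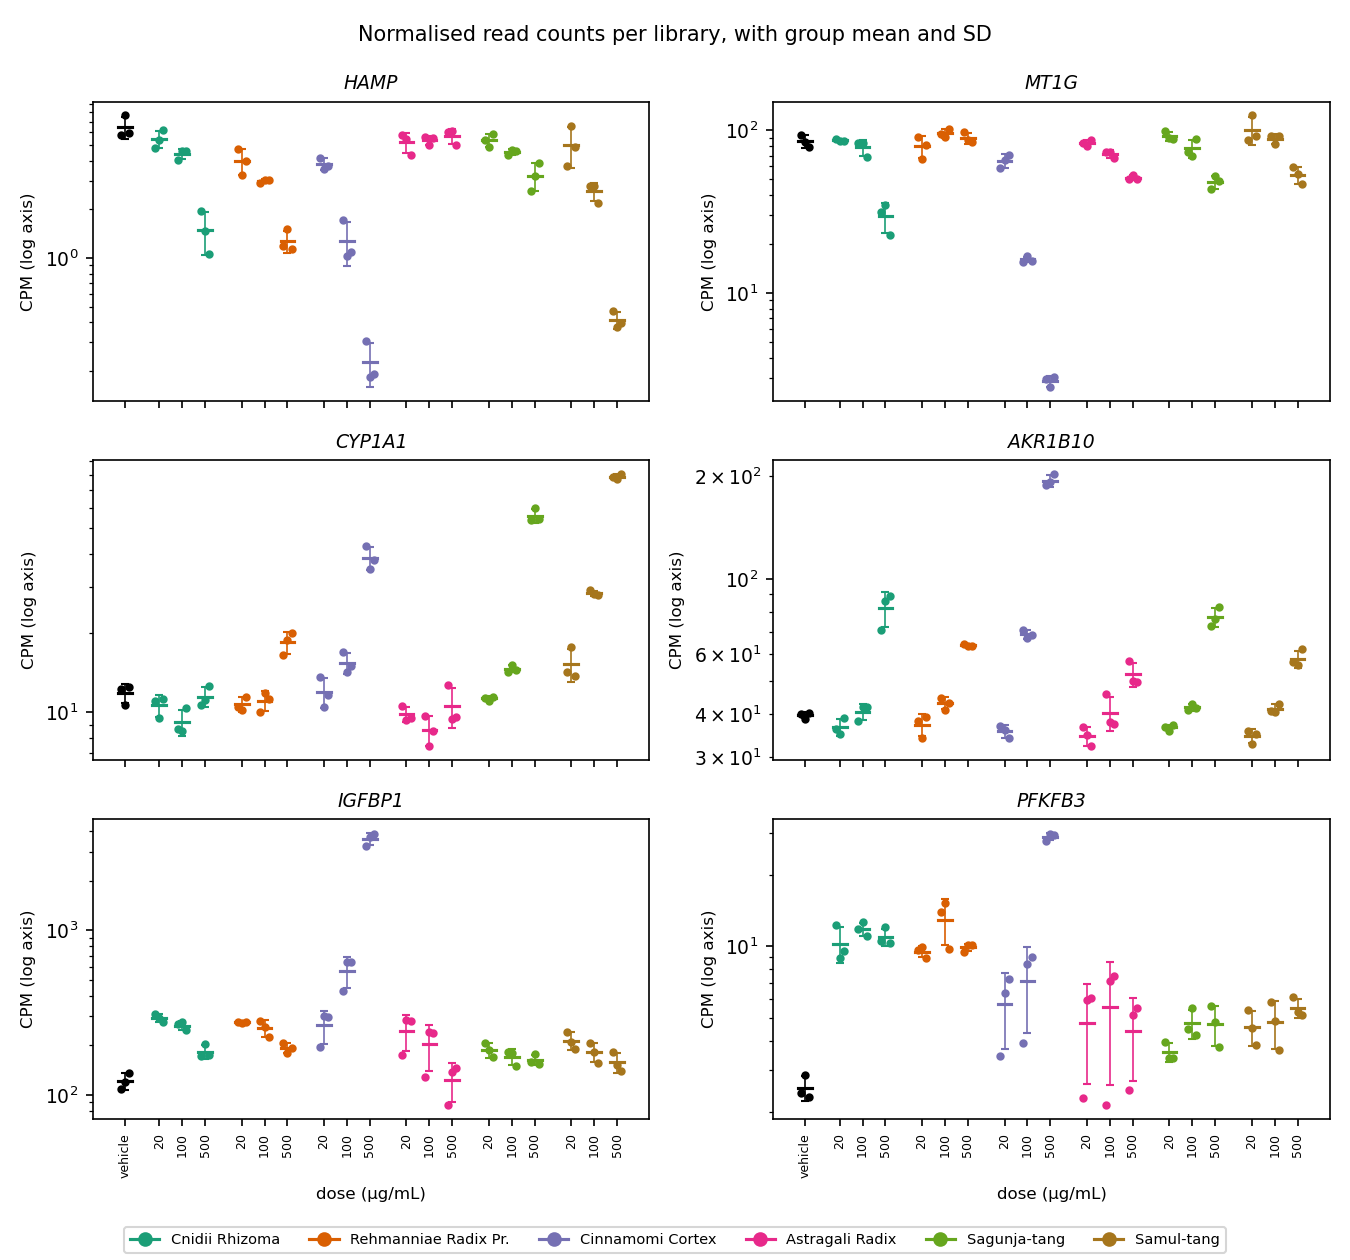
Normalised read counts (CPM, log axis) of HAMP, MT1G, CYP1A1, AKR1B10, IGFBP1 and PFKFB3 in vehicle and at 20, 100 and 500 µg/mL (horizontal axis) of each extract. Points are single libraries and bars the group mean and SD. HAMP falls to 0.413 ± 0.0476 CPM with Samul-tang and 0.227 ± 0.0695 with Cinnamomi Cortex, and PFKFB3 with Astragali Radix lies at 2.47 CPM in replicate 1 and 5.15 and 5.52 CPM in the other libraries at 500 µg/mL.

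Across extracts, the NRF2 list rose with dose in all 6, with a median trend per step between 0.09 (Astragali Radix, adjusted p = 5.25e-17) and 0.39 (Cinnamomi Cortex, adjusted p = 3e-19). The number of its 21 genes with a rising trend was 13 for Cnidii Rhizoma, 12 for Rehmanniae Radix Preparata, 19 for Cinnamomi Cortex, 5 for Astragali Radix, 14 for Sagunja-tang and 13 for Samul-tang. Adjusted over the list alone these counts were 16, 19, 19, 13, 15 and 13. Metallothionein genes fell with dose in 5 extracts, and 7 of 8 passed in 4 of them (7 adjusted over the list alone). With Astragali Radix 6 did (7 adjusted over the list alone). The median trend was -1.2 for Cinnamomi Cortex (adjusted p = 4.75e-08) and -0.62 for Cnidii Rhizoma (adjusted p = 1.73e-51). It was -0.31 for Astragali Radix (adjusted p = 7.68e-21), -0.39 for Sagunja-tang (adjusted p = 1.12e-26) and -0.37 for Samul-tang (adjusted p = 7.54e-14). For Rehmanniae Radix Preparata the median was -0.01 (adjusted p = 0.93). The cholesterol synthesis list fell with dose in 5 extracts and rose with Cinnamomi Cortex, by a median of -0.13 (Cnidii Rhizoma, adjusted p = 4.95e-35), -0.04 (Rehmanniae Radix Preparata, adjusted p = 2.89e-05), 0.17 (Cinnamomi Cortex, adjusted p = 3.48e-06), -0.08 (Astragali Radix, adjusted p = 1.21e-15), -0.07 (Sagunja-tang, adjusted p = 5.79e-12) and -0.07 (Samul-tang, adjusted p = 4.01e-14). For Rehmanniae Radix Preparata 0 of its 22 members passed (0 adjusted over the list alone), and for Cnidii Rhizoma 19 (21). The fatty acid synthesis list also fell with dose in these 5, by a median of -0.09 (Cnidii Rhizoma, adjusted p = 3.36e-24), -0.02 (Rehmanniae Radix Preparata, adjusted p = 0.000582), -0.03 (Astragali Radix, adjusted p = 4.1e-07), -0.06 (Sagunja-tang, adjusted p = 6.78e-11) and -0.08 (Samul-tang, adjusted p = 1.57e-12). The mitosis list rose with dose for Sagunja-tang (9 of 26 genes, 15 adjusted over the list alone, adjusted p = 1.18e-11) and fell for Cinnamomi Cortex (all 26, adjusted p = 9.11e-38). Without Samul-tang at 20 µg/mL replicate 2 the number of NRF2 genes rising with Samul-tang was 11, and of metallothionein genes falling 5. Without the replicate 1 libraries of set 6, chosen after seeing the data, 3 NRF2 genes rose and 3 metallothionein genes fell with dose of Astragali Radix. Of 150 pairs of list and high-dose contrast 67 passed, and 54 of these held with an estimated correlation.

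With all libraries, the lists of p53 targets, interferon response genes, drug metabolism genes of the nuclear receptors PXR and CAR, replication-dependent histones and markers of other cell types passed for none of the 6 extracts at 500 µg/mL. Without the replicate 1 libraries of set 6, left out after seeing the data, p53 targets were lower with Astragali Radix (3 of 22, adjusted p = 0.0235). With Cinnamomi Cortex, 7 of 22 rose and 7 fell (7 and 7 adjusted over the list alone, adjusted p = 0.325) among p53 targets. Of interferon response genes 6 of 16 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.964). Of histone genes 7 of 14 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.132). Drug metabolism genes went both ways: 3 of 10 rose and 6 fell (3 and 6 adjusted over the list alone, adjusted p = 0.325) with Cinnamomi Cortex. With Samul-tang 2 of 10 rose and 5 fell (2 and 5 adjusted over the list alone, adjusted p = 0.29), where the glucuronosyltransferase UGT1A1 rose by 0.58 ± 0.081 and the exporter ABCB1 by 0.42 ± 0.043. Among markers of other cell types, 2 of 10 rose and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.902) with Cnidii Rhizoma. With Sagunja-tang 0 of 10 rose and 2 fell (0 and 2 adjusted over the list alone, adjusted p = 0.712).

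**Figure D3:**
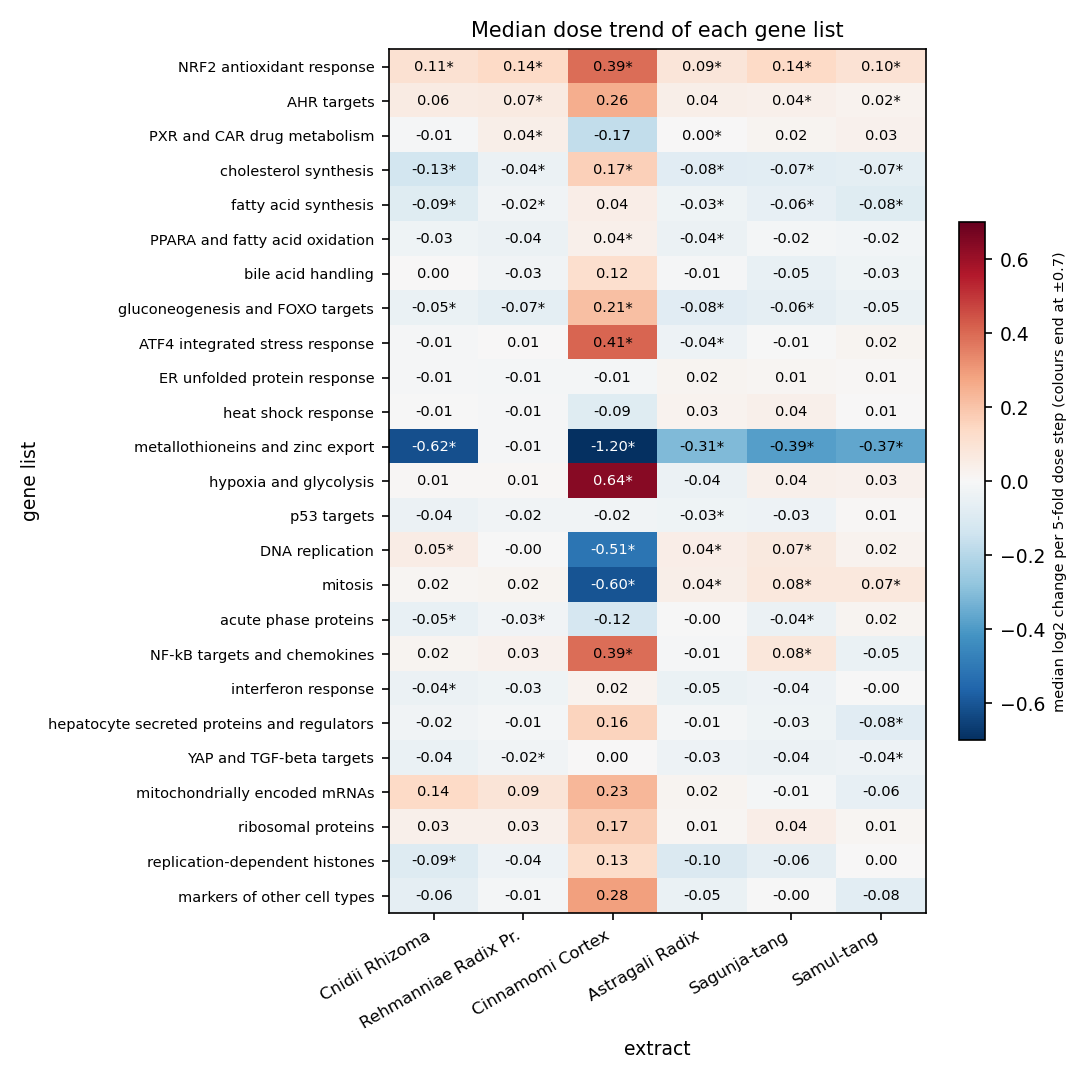
Median dose trend (log2 change per 5-fold dose step, printed and as colour) of the 25 lists (vertical axis) in the 6 extracts (horizontal axis). A star marks a list test with an adjusted p under 0.05 at both the preset and the estimated correlation. Metallothioneins are lowest with Cinnamomi Cortex (-1.2), and NRF2 genes are above 0 in all 6 columns.

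Samul-tang holds both herbs of set 5, so its dose trends were compared with theirs across genes, which are not independent replicates. Pearson's r across the 16167 genes was 0.07 with Cnidii Rhizoma (two-sided exact permutation p = 0.464, adjusted 0.522) and 0.017 with Rehmanniae Radix Preparata (exact permutation p = 0.788). With 1 replicate number left out of both extracts these were -0.04 to 0.107 and -0.053 to 0.062. Over genes with at least 10 CPM they were 0.215 (exact permutation p = 0.257) and -0.006 (exact permutation p = 0.98). The Samul-tang trend in all of these depends on replicate 2 at 20 µg/mL. Of 15 pairs of extracts, 6 passed after adjustment over the 15 in the same exact permutation test. They were Sagunja-tang with Samul-tang (r = 0.209, p = 0.00357, adjusted 0.0134), Astragali Radix with Sagunja-tang (r = 0.201, p = 0.00238, adjusted 0.0134) and Cnidii Rhizoma with Sagunja-tang (r = 0.165, p = 0.00476, adjusted 0.0143). The others were Cnidii Rhizoma with Astragali Radix (r = 0.154, p = 0.00238, adjusted 0.0134), Rehmanniae Radix Preparata with Sagunja-tang (r = 0.136, p = 0.0131, adjusted 0.0328) and Rehmanniae Radix Preparata with Astragali Radix (r = 0.113, p = 0.00357, adjusted 0.0134). In the same way, and with no p computed, r ran from 0.101 to 0.158 for Sagunja-tang with Samul-tang, from 0.111 to 0.188 for Astragali Radix with Sagunja-tang and from 0.107 to 0.191 for Cnidii Rhizoma with Sagunja-tang. The ranges were 0.077 to 0.122 for Cnidii Rhizoma with Astragali Radix, 0.071 to 0.13 for Rehmanniae Radix Preparata with Sagunja-tang and 0.074 to 0.103 for Rehmanniae Radix Preparata with Astragali Radix. These correlations carried at most 4.4% of the variance between genes. Over the 9148 genes with at least 10 CPM, 3 pairs passed: Cnidii Rhizoma with Astragali Radix (r = 0.624) and with Sagunja-tang (0.587), and Astragali Radix with Sagunja-tang (0.558).

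At 20 µg/mL all 6 extracts differed from vehicle in 635 to 3353 genes and from each other in fewer. The counts against vehicle were 1050 for Cnidii Rhizoma, 1161 for Rehmanniae Radix Preparata, 1157 for Cinnamomi Cortex, 635 for Astragali Radix, 1837 for Sagunja-tang and 3353 for Samul-tang. The 6 lists shared 157 higher and 87 lower genes, 244 in all. With only the compared groups in each fit, chosen after seeing the data, they shared 59 and 241 of 244 kept direction. Samul-tang apart, the other 5 shared 275 with all groups and 179 with only those compared. All 6 comparisons use the same 3 vehicle libraries, and no number expected by chance is given. The higher count of Samul-tang at 20 than at 500 µg/mL did not hold with only the compared groups in the fit (142 and 1479) or with limma-trend (6 and 978), under which at most 6 genes could be shared by all. At 100 µg/mL 74 genes were higher and 36 lower in all 6 extracts, and at 500 µg/mL 73 and 38. Between extracts at 20 µg/mL, edgeR called 0 genes within each set (834, 542 and 2838 at an unadjusted p under 0.05 for sets 5, 6 and 7) and 0 in the 4 pairs across sets 5 and 6 (715 to 933 unadjusted). These pairs were chosen after seeing the data and run in edgeR alone. Against the herbs, Sagunja-tang differed in 14 to 101 genes and Samul-tang in 188 to 575. The median of the hypoxia list lay above the vehicle mean in every library at 20 µg/mL, from 0.01 (Sagunja-tang, replicate 3) to 0.38 (Cnidii Rhizoma, replicate 1), beside -0.05, 0.02 and 0.00 in the vehicle libraries themselves. PFKFB3 was at 10.3 ± 1.78 CPM with Cnidii Rhizoma and 2.54 ± 0.3 with vehicle.

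Single libraries moved the counts at the lower doses by more than 1.5 times. At 20 µg/mL, Cnidii Rhizoma (1050) gave 498 and 697 without vehicle replicate 1 or 2 and 618 and 535 without its own replicate 1 or 2. Rehmanniae Radix Preparata (1161) gave 582 and 575 without vehicle replicate 1 or 2 and 683 and 643 without its own replicate 1 or 2. Cinnamomi Cortex (1157) gave 480 and 653 without vehicle replicate 1 or 2 and 512 and 423 without its own replicate 2 or 3. Astragali Radix (635) gave 279 and 254 without vehicle replicate 1 or 2 and 247 and 335 without its own replicate 2 or 3. Sagunja-tang (1837) gave 1116 and 964 without vehicle replicate 1 or 2 and 1066 and 1095 without its own replicate 1 or 2. Samul-tang (3353) gave 1927 without vehicle replicate 1 and 1945 without its own replicate 2. At 100 µg/mL, Cnidii Rhizoma (578) gave 243 and 307 without vehicle replicate 1 or 2 and 234, 313 and 340 without its own replicate 1, 2 or 3. Rehmanniae Radix Preparata (674) gave 300 and 395 without vehicle replicate 1 or 2 and 398, 367 and 396 without its own replicate 1, 2 or 3. Astragali Radix (366) gave 136 and 154 without vehicle replicate 1 or 2 and 98 and 103 without its own replicate 2 or 3. Sagunja-tang (1431) gave 771 and 694 without vehicle replicate 1 or 2 and 545 and 931 without its own replicate 1 or 3. Samul-tang (1307) gave 604 and 721 without vehicle replicate 1 or 2 and 810, 694 and 711 without its own replicate 1, 2 or 3.

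Palmul-tang joins the herbs of Sagunja-tang and Samul-tang, and its single library per dose allows description but no test. CYP1A1 stood at 66.6 CPM at 500 µg/mL beside 11.8 ± 1.03 in vehicle, with log2 ratios to the vehicle mean of 2.49, 0.79 and 0.23 at 500, 100 and 20 µg/mL. The 2.49 stood beside 2.25 for Sagunja-tang and 2.73 for Samul-tang. PFKFB3 stood at 2.29, 2.34 and 1.71 over the same doses, TMCC1 at 1.31, 1.39 and 1.02, the tubulin gene TUBB1 at 1.22, 1.43 and 0.98 and HES4 at 1.12, 0.83 and 0.78. Among genes with a mean of at least 5 CPM and all 3 doses below all vehicle libraries, the lowest at 500 µg/mL were the kininogen gene KNG1 (-0.93), SCNN1A (-0.77), the glucose transporter SLC2A4 (-0.75), MVP-DT (-0.67) and DKK1 (-0.66). Outside this rule, and picked after their values were seen, HAMP stood at -3.49 (0.502 CPM beside 6.48 in vehicle) and MT1F at -0.99 (25.4 CPM beside 50.9). At 500 µg/mL the NRF2 list had a median ratio of 0.17, metallothioneins -0.43 and cholesterol synthesis -0.16. The first lay at percentile 100 and the others at 0, to 1 decimal, of 10000 random lists matched on expression. In all, 11 of the 25 lists lay at 1 of these ends. At 100 and 20 µg/mL the medians were -0.03 and -0.04 for NRF2, 0.01 and 0.03 for metallothioneins and -0.03 and 0.01 for cholesterol synthesis. The hypoxia list was at 0.39, 0.34 and 0.33 over the 3 doses. Across genes, the log2 ratios at 500 µg/mL correlated with the fold changes of Sagunja-tang at r = 0.586 and of Samul-tang at r = 0.571. With the herbs r was 0.553 for Rehmanniae Radix Preparata, 0.453 for Cnidii Rhizoma, 0.432 for Astragali Radix and 0.277 for Cinnamomi Cortex. Simulated unchanged groups with a shared vehicle gave a mean of 0.361 and at most 0.415. They hold no difference between sets, so they set no bound for r. The covariances were 0.0575 for Sagunja-tang, 0.0592 for Samul-tang and 0.0716, the largest, for Cinnamomi Cortex beside a simulated 0.0238.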

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

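Chosen only after the result was seen were the tests on pairs of extracts at 20 µg/mL, on vehicle as a whole, on set 6, on 1 library of Samul-tang, on SLC30A1 and on metallothioneins beside other genes, and the comparator made from the groups at 20 µg/mL. List tests in this part use an estimated correlation. Dose trends differed between the herbs of set 5 for 11 genes (1082 at an unadjusted p under 0.05). Metallothioneins had the lower trend with Cnidii Rhizoma than with Rehmanniae Radix Preparata (-0.58 per step, adjusted p = 1.24e-08). So did cholesterol synthesis (-0.09, adjusted p = 2.48e-05), fatty acid synthesis (-0.05, adjusted p = 7.18e-05) and AHR targets (-0.01, adjusted p = 0.0463). DNA replication genes had the higher trend (0.05, adjusted p = 0.0204). Between Cinnamomi Cortex and Astragali Radix, trends differed for 8230 genes (9048 unadjusted). Higher with Cinnamomi Cortex were the trends of hypoxia (0.71, adjusted p = 0.00125) and ATF4 genes (0.50, adjusted p = 3.26e-06). So were those of NF-kB targets (0.44, adjusted p = 0.00118), NRF2 genes (0.38, adjusted p = 9.98e-07) and cholesterol synthesis (0.24, adjusted p = 0.00133). The same held for gluconeogenesis and FOXO targets (0.30, adjusted p = 0.0204) and PPARA targets (0.07, adjusted p = 0.026). Lower were mitosis (-0.65, adjusted p = 3.12e-08) and DNA replication genes (-0.55, adjusted p = 7.42e-07). Between Sagunja-tang and Samul-tang, trends differed for 23 genes (1971 unadjusted), and the trends of NF-kB targets (0.08 per step, adjusted p = 0.000633) and NRF2 genes (0.06 per step, adjusted p = 0.0199) were higher with Sagunja-tang.

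Of the 635 to 3353 genes changed against vehicle at 20 µg/mL, 244 changed in the same direction with all 6 extracts, PFKFB3 with Cnidii Rhizoma among the genes raised at every dose. With only the compared groups fitted, also chosen after seeing the data, 59 were shared and 241 of 244 kept direction. The 244 genes were picked for changing alike in all 6 extracts. That choice, and not a test, left out constituents particular to 1 extract. The 15 pairs of extracts at 20 µg/mL differed in a median of 14 genes, beside a median of 1159 against vehicle. At an unadjusted p under 0.05 in edgeR the pairs differed in 542 to 3370 genes. A response that grows with dose was seen in only 1 extract, Cinnamomi Cortex (median signed trend 0.09, the others -0.05 to -0.02). In total count 3 of 3 vehicle libraries, and in the share of the 10 highest genes 2 of 3, lay inside the range at 20 µg/mL. Lying inside it excludes neither depth nor dominant genes as a cause. Handling may account for part: in set 6 the replicate 1 libraries were the lowest of 3 in the 244 genes in 6 of 6 groups (exact p = 0.00412). The 244 genes thus moved with the library as well as with the extract (sets 5 and 7 gave exact p = 0.3 and 0.877). With a single vehicle group outside the sets, vehicle cultures or libraries that stand apart and a response already complete at 20 µg/mL cannot be told apart for the 244 genes, so the dose trends are the safer reading of each extract.

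The dose trend of Samul-tang may owe its size to replicate 2 at 20 µg/mL: 153 genes had a trend without it, beside 2812 and 2904 without replicate 3 or 1. Low depth is ruled out by its 33.1 M counts (median of all libraries 25.5). RNA from other cell types stays open: marker genes lay 0.23 above its companions (median of 10 genes, SD 0.36, on the log2 scale), under the 0.5 set beforehand but the highest of 57 libraries, the next being at 0.14. A wrong label cannot be told apart: its distance to Samul-tang at 100 µg/mL was 0.395 and to its own group 0.4, but only 24 of 57 libraries are nearest to their own group. HAMP, ID1, ID3 and CYP1A1 kept trends of similar size without the library.

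The fall of the metallothioneins with dose in 5 extracts, a candidate sign of less zinc or other metal reaching the regulator MTF1, was set against reads shared between near-identical copies and against scaling. SLC30A1, a zinc exporter with the same regulator, fell with dose in 4 of the 5. Its trends were -0.22 (Cnidii Rhizoma), -0.26 (Cinnamomi Cortex), -0.13 (Astragali Radix), -0.13 (Sagunja-tang) and 0.03 (Samul-tang, adjusted p = 0.649). Having another sequence, it cannot test reads shared by the copies. The list median lay below the median of all other genes in each of the 5, the difference nearest 0 being -0.31 with Astragali Radix (SE 0.07). These 5 had been picked by a list test that itself compares the list with all other genes. The sign of the difference was thus fixed by that choice, and it decides nothing on depth or scaling. Zinc was not measured, so a response to metal stays a hypothesis.

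Other groupings of the same libraries were counted with limma-trend. For each dose trend 1 of 100 groupings, the real one, gave as many genes, the smallest share that 100 groupings can show. The counts of trends from edgeR were not tested in this way. The real counts and the highest of the others were 233 and 73 for Cnidii Rhizoma, 68 and 24 for Rehmanniae Radix Preparata, 10036 and 2 for Cinnamomi Cortex, 76 and 42 for Astragali Radix, 601 and 67 for Sagunja-tang and 64 and 9 for Samul-tang. Groups of 3 against 3 have 10 groupings, too few for a share under 0.05. Their real counts and highest others against vehicle follow for 500, 100 and 20 µg/mL. Cnidii Rhizoma gave 391 and 1, 342 and 0 and 796 and 2. Rehmanniae Radix Preparata gave 680 and 0, 370 and 3 and 267 and 2. Cinnamomi Cortex gave 10071 and 0, 2332 and 1 and 506 and 1. Astragali Radix gave 37 and 0, 62 and 1 and 69 and 2. Sagunja-tang gave 685 and 2, 1301 and 1 and 1929 and 0. Samul-tang gave 978 and 1, 1276 and 0 and 6 and 2. For the pairs at 500 µg/mL they were 8 and 1 for the herbs of set 5, 9871 and 1 for those of set 6 and 5 and 1 for the formulas of set 7.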

How the results depend on the processing

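The comparator made from the groups at 20 µg/mL, the pairs of extracts at 20 µg/mL, the shared genes with only the compared groups and the removal of set 6 replicate 1 were chosen after seeing the data, and the other alternatives before the data were examined. All 27 counts stayed within 1.5 times under RLE size factors and with the replicate number as a block. Over all groups 12 of 513 pairs with the same replicate number correlated above 0.1, which leaves a pairing within a set open, as replicate 1 stood apart in set 6. With the block the counts were, for example, 2052 for Cnidii Rhizoma at 500, 1743 for the Samul-tang trend and 66 called lists. With only the compared groups in the fit the counts that moved were 752 for Cnidii Rhizoma at 500, 628 for Rehmanniae Radix Preparata at 20, 278 for Astragali Radix at 500, 395 for Astragali Radix at 20, 1014 for Sagunja-tang at 500, 142 for Samul-tang at 20, 320 for the Cnidii Rhizoma trend, 97 for the Astragali Radix trend, 72 for the Samul-tang trend, 19 for Cnidii Rhizoma against Rehmanniae Radix Preparata and 11 for Sagunja-tang against Samul-tang, where fewer libraries estimate the dispersion. With no filter on low counts they were 559 for Astragali Radix at 100, 281 for the Rehmanniae Radix Preparata trend, 292 for the Astragali Radix trend, 368 for Cnidii Rhizoma against Rehmanniae Radix Preparata and 233 for Sagunja-tang against Samul-tang, and with DESeq2 217 for Sagunja-tang against Samul-tang. Without the replicate 1 libraries of set 6 the count moved to 110 for the Astragali Radix trend. Against the mean of the 6 groups at 20 µg/mL the counts were 87 for Cnidii Rhizoma at 100, 537 for Rehmanniae Radix Preparata at 500, 79 for Rehmanniae Radix Preparata at 100, 1290 for Astragali Radix at 500, 87 for Astragali Radix at 100, 118 for Sagunja-tang at 100, 1105 for Samul-tang at 500 and 70 for Samul-tang at 100, a comparator of 18 libraries that leaves out what all extracts share at 20 µg/mL. Over genes with at least 10 CPM, 3 pairs of extracts were similar, 3 pairs lost their call and Rehmanniae Radix Preparata with Samul-tang turned to -0.006. With a prior count of 0.5 the correlations of Palmul-tang were 0.551 and 0.517. The cause was not tested for these or for the counts above where none is named.

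Of 554 named values, 473 kept direction and call with only the compared groups and 81 lost the call, 534 and 20 with no filter, and 553 and 1 under RLE and with the block. DESeq2 kept 546 of 550. Without each single library in turn, 420 of 554 kept their call throughout. Of 67 list calls, 66 held under RLE and 66 with the block, 54 with an estimated correlation, and all 62 that could be tested without ribosomal and mitochondrial genes held. Against the mean of the groups at 20 µg/mL, 320 of 524 gene values kept their call, 156 lost it and 48 changed sign. The last are given on the log2 scale. With Cnidii Rhizoma these were NR0B2 -0.13, IGFBP1 -0.42, HSPA1B -0.02, HSPA1A -0.15, CCNE1 0.03, PCNA 0.14 and MX1 0.01. With Rehmanniae Radix Preparata these were CCDC144NL 0.05, CPT1A -0.05, IGFBP1 -0.34, CEBPB 0, HERPUD1 -0.06, DNAJB9 -0.05, HSPA1B -0.06, HSPA1A -0.12, RRM1 0.01, MCM6 0.02, AMOTL2 0.04 and RPS13 0.03. With Astragali Radix these were TRIM8-DT -0.11, HSPA1A -0.16, FAM13A -0.16, HSPA1B -0.07, CCDC144NL 0.13, TRIM36 0.14, CEBPB -0.3, DNAJB9 -0.03, EDEM1 -0.02, PCNA 0.09, CCNE1 0.01, AMOTL2 0.02 and ANKRD1 0. With Sagunja-tang these were ACSL1 0.01, PLIN2 -0.06, CEBPB -0.24, HSPA1B -0.05, HSPA1A -0.13, PCNA 0.02, ANKRD1 0.01, SMAD7 -0.05 and RPS3A 0.01. With Samul-tang these were PFKFB3 -0.1, ACAA2 0.04, NR0B2 -0.29, CEBPB -0.15, HSPA1B -0.1, HSPA1A -0.17 and MX1 0.03.

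Leaving out 1 library at a time gave the lowest and highest counts that follow. Cnidii Rhizoma had 937 and 2181 at 500, 234 and 409 at 100, 498 and 820 at 20, and 226 and 771 for the trend. Rehmanniae Radix Preparata had 536 and 851 at 500, 300 and 500 at 100, 575 and 1038 at 20, and 69 and 108 for the trend. Cinnamomi Cortex had 9476 and 9669 at 500, 2161 and 2935 at 100, 423 and 1119 at 20, and 9365 and 10049 for the trend. Astragali Radix had 208 and 410 at 500, 98 and 434 at 100, 247 and 680 at 20, and 101 and 180 for the trend. Sagunja-tang had 1225 and 1934 at 500, 545 and 1303 at 100, 964 and 1705 at 20, and 425 and 787 for the trend. Samul-tang had 1151 and 2160 at 500, 604 and 1154 at 100, 1927 and 3616 at 20, and 153 and 2904 for the trend. For the pairs at 500 the counts were 42 and 246 in set 5, 9461 and 9656 in set 6, and 69 and 110 in set 7, for list calls 66 and 72, and for the correlations of Palmul-tang 0.619 and 0.644 with Sagunja-tang and 0.597 and 0.632 with Samul-tang. For the edgeR contrasts another pseudocount and a filter on the mean were not run, because the table holds counts. Dose trends of single genes were rerun only for Samul-tang without replicate 2 at 20 µg/mL. Depth limits genes with few reads, such as HAMP in treated groups, and the self-test recovered 34% of 1.2-fold changes.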

Other observations

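Only the comparator made from the groups at 20 µg/mL was chosen after seeing the data in this part, and the genes were picked from the lists after their values were seen. Cinnamomi Cortex at 500 µg/mL lowered the glutathione transferases GSTA1 (-2.05 ± 0.098) and GSTA2 (-2.60 ± 0.12) of the PXR and CAR list, and raised the stress cytokine GDF15 (2.49 ± 0.077). The lipogenic transcription factor MLXIPL changed by -1.92 ± 0.074 and the chaperone HSP90AA1 by -1.22 ± 0.065. Of 10 other-cell markers 3 fell and 5 rose, such as LYZ (1.37 ± 0.074, 1220 CPM in vehicle), PDGFRB (1.36 ± 0.11), CD68 (1.28 ± 0.11) and KRT19 (1.19 ± 0.079), with no list call (adjusted p = 0.0927).

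G6PC1 rose with Cinnamomi Cortex (1.42 ± 0.1) and fell with the other 5 extracts, with values from -0.65 ± 0.11 (Sagunja-tang) to -0.43 ± 0.11 (Samul-tang). The calls with Rehmanniae Radix Preparata and Samul-tang ended without vehicle replicate 3 (-0.35 and -0.27). SLC51A, a bile acid exporter subunit, rose with Cnidii Rhizoma (0.62 ± 0.075) and Cinnamomi Cortex (1.39 ± 0.073). UGT1A1 rose with Sagunja-tang (0.58 ± 0.08), Samul-tang (0.58 ± 0.081) and Cinnamomi Cortex (0.47 ± 0.082). ABCB1 rose with all extracts but Astragali Radix, from 0.15 ± 0.043 with Cnidii Rhizoma to 0.61 ± 0.043 with Cinnamomi Cortex, and its call with Cnidii Rhizoma ended without vehicle replicate 2 (0.14) or treated replicate 2 (0.14), with only the compared groups in the fit (0.16), with no filter on low counts (0.14) and against the mean of the groups at 20 µg/mL (0.01).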
